A study of Arabidopsis thaliana with 12 samples.

How the data were processed

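Gene expression was measured on one-channel arrays with total RNA of Arabidopsis thaliana, 6 arrays of wild type Columbia-0 and 6 of the psaf antisense line, per the labels. The deposited table gives 1 linear intensity for each of 3439 probes on each array. The values were taken as already normalised by the authors, since the 12 totals agreed within 0.07 log2 and the mean intensity per probe was 1.04 to 1.09. How the authors scanned the arrays, corrected background and scaled the intensity values is not given in the sources used here, and neither is the array's probe layout. Of the scale, what stays unknown is the normalisation method and whether 0 stands for a missing or a low value. Intensities ran from 0 to a ceiling of 100, which 9 values on 2 probes reached. On all 12 arrays 109 probes were listed at 0, and 198 were at 0 on at least 1 array.

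Values of 0 were treated as not measured, and a probe was tested with at least 4 measured arrays in each genotype, which left 3266 probes and set 173 aside. Log2 intensities on the deposited scale were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, genotype as the single term), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. This fit over 12 arrays was fixed before the data were examined, as were the gene lists, the rule for named genes and these alternatives: the replicate number as a block, quantile normalisation, median centring, cyclic loess, an offset of 0.106 before log2, leaving out the dimmest 25% of probes, keeping probes measured on all arrays, a trended and robust variance, array weights, a close pair as a random block or averaged, leaving out each array, an exact Wilcoxon test, a threshold of 0.01 and a minimum fold of 1.5. Alternatives added after seeing the data were averaged pairs combined with each other scaling, a correction for neighbouring probes, leaving out probes at the ceiling, leaving out each close pair, joined gene lists, a background of named probes for the list test, and the offset with pairs averaged for other genes named at the end. The neighbour correction subtracted from each array's log2 value the median deviation of the 4 nearest probe numbers from their genotype's median.

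Close pairs were found as arrays that were each other's nearest by the robust SD of their log2 difference. The correlation of the 2 arrays of a pair, estimated over all probes by limma, was 0.76. Means ± SD in the text are over the 3 pair means of a genotype, each pair mean being the geometric mean of its arrays, and the SE is that of the fit with pairs averaged. A verb of change was used for a named gene only where both the 12-array fit and the pairs-averaged fit passed, and the counts over all 4 scalings, with and without averaging, were chosen after seeing the data.

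Probes were named from the platform annotation supplied with the table. It gave 1 gene for 692 probes and several for 870, and 1877 probes were unnamed here; no gene was named from a probe with several. Of the 692, 690 matched a RefSeq gene table of assembly TAIR10.1, which was used for symbols only, and 649 were tested. Coordinates are not reported because no genome build is given in the sources used here. Of the 270 genes in 14 lists, 15 were on named probes and 14 were tested; the remaining 1, PRPL29 (AT5G65220), was not tested. The rule for named genes took PSAF, then the 6 largest rises and 6 largest falls among genes past the threshold with at least 5 of 6 psaf arrays on that side of the WT mean, then members of lists with at least 5 measured genes. PSAF was on 0 named probes, and no list had 5 measured members, so every tested list member was described instead, a choice made after seeing which probes were named. List tests used limma camera with a preset correlation of 0.01, camera with an estimated correlation, and fry on median-centred values, which tests whether the genes move one way and does not compare them with other genes.

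The fits were tested on simulated data for the psaf against WT comparison with 3266 probes, 100 changed by 0.5 log2 and 100 by 1 log2. With independent arrays, the 12-array fit recovered 73% and 90% of them, and 6.86% of its calls were false. With arrays simulated in close pairs, it recovered 82% and 89%, and 46.9% of calls were false. With pairs averaged in the same simulation, 28% and 78% were recovered and 2.75% of calls were false. These simulations had few changed probes, no shift of the median probe and errors independent between probes. Their shares of false calls therefore do not carry over to the data. The neighbour correction reduced a simulated drop of -2.01 log2 over runs of probes to -0.25. Its effect on unaffected probes beside such a run was not measured.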

Results

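Transcript levels were compared between the psaf line of Arabidopsis thaliana and wild type plants of the Columbia-0 accession (WT). The psaf line carries an antisense construct and lacks PSI-F, a subunit of photosystem I on the side where plastocyanin docks. The question addressed was which nuclear transcripts differ in abundance when this subunit is missing. Total RNA was hybridised to 12 one-channel arrays, 6 of WT and 6 of psaf, each numbered 1 to 6. The deposited table held normalised intensities of 3439 probes, of which 3266 were tested. The tissue sampled, the growth conditions and the number of plants behind each array are not given in the sources used here.

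The summed intensity of an array lay between 3563 and 3745, and 4.45% to 5.18% of probes were listed at 0. The median probe intensity was 0.536 to 0.569 on WT arrays and 0.416 to 0.459 on psaf arrays. The median over tested probes of the log2 difference was -0.29, which is not the difference between these array medians. After median centring, which removes each array's own median, it was 0.058. Within each genotype, arrays 1 and 2, arrays 3 and 4, and arrays 5 and 6 formed close pairs. The robust SD of the log2 difference was 0.0988 to 0.122 within a pair. It was 0.219 to 0.375 between other WT arrays, 0.186 to 0.241 between other psaf arrays and 0.457 to 0.626 between genotypes. Each pair was therefore counted as 1 sample in every mean ± SD (n = 3 pair means per genotype). The labels do not say that arrays or pairs came from separate plants, so the p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

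The steepest loss among single named genes was in Z-ISO (AT1G10830), the zeta-carotene isomerase of carotenoid biosynthesis, which fell from an intensity of 2.33 ± 0.367 in WT to 0.417 ± 0.122 in psaf (SD, n = 3). AT3G52960, encoding the plastid peroxiredoxin PRXIIE, fell from 2.93 ± 0.594 to 1.15 ± 0.0681. PRK (AT1G32060), the phosphoribulokinase of the Calvin-Benson cycle, rose from 0.762 ± 0.197 to 1.25 ± 0.0276. In all, 1997 of the 3266 probes differed between genotypes in limma over the 12 arrays, 359 higher and 1638 lower in psaf (adjusted p under 0.05). With each close pair averaged, 1271 probes passed, 157 higher and 1114 lower.

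The balance of higher and lower probes depended on the scaling of the arrays. On the deposited scale 18.0% of the 1997 calls were higher in psaf. After quantile normalisation 725 probes were higher and 854 lower, so that 45.9% of calls were higher. After median centring 926 were higher and 722 lower, or 56.2%, and after cyclic loess 823 were higher and 797 lower, or 50.8%. Across all 4 scalings, each fitted over 12 arrays and over pair means, 130 probes were higher and 310 were lower in psaf in every fit. Among probes with 1 named gene these were 22 and 69. In the fits over 12 arrays alone, a further 39 probes were called in opposite directions by different scalings. The count of 130 could not exceed the 157 probes higher on the deposited scale with pairs averaged. That of 310 could not exceed the 329 lower under median centring with pairs averaged. The balance of 130 to 310 therefore still depends on the scaling. Directions below that held in all 8 fits are given as such. The shift of the median probe was -0.29, but the median shift was -0.34 in the dimmest of 10 brightness classes and 0.19 in the brightest. No single shift is therefore a reference for every log2 difference.

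**Figure D1:**
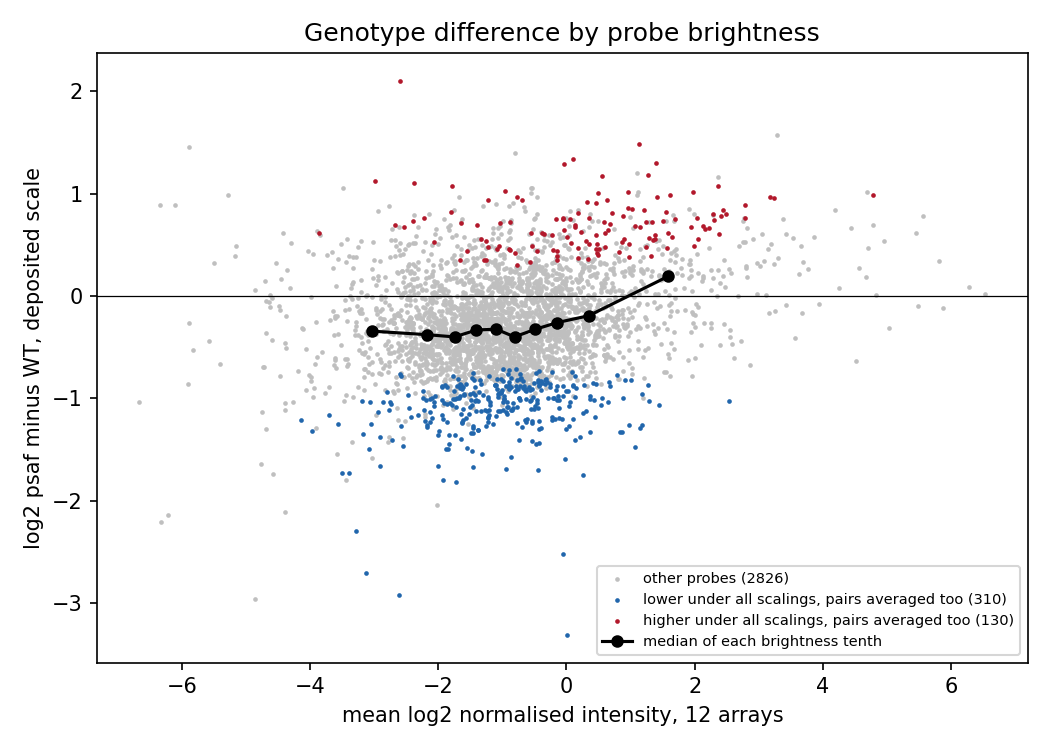
Log2 difference of psaf minus WT on the deposited scale (vertical axis) against the mean log2 normalised intensity over 12 arrays (horizontal axis), with 1 point per tested probe. Black circles give the median of each of 10 brightness classes of equal size, from -0.34 in the dimmest to 0.19 in the brightest; red and blue points are the 130 higher and 310 lower probes called in every scaling with and without averaging of pairs.

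Of the 6 named genes with the largest rise, 3 were higher in all 8 fits. AT4G09620 rose from 1.63 ± 0.304 to 3.66 ± 0.316, a log2 difference of 1.18 ± 0.17 (SE over pair means, limma adjusted p = 0.00409 with pairs averaged). AT4G13550, annotated as a lipase, rose from 0.131 ± 0.0105 to 0.282 ± 0.0351, a log2 difference of 1.1 ± 0.14 (adjusted p = 0.0032); for this dim probe an offset of 0.106 before log2 gave 0.71. AT1G01730 rose from 0.736 ± 0.326 to 1.71 ± 0.0593, a log2 difference of 1.34 ± 0.36 (adjusted p = 0.0279). Its WT arrays 3 and 4 read 0.370 and 0.359 against 0.854 to 0.991 on the other 4, and a correction for neighbouring probe numbers, added after seeing the data, lowered the difference to 0.97. All 6 psaf arrays lay above the WT mean for these 3 genes.

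The other 3 passed over 12 arrays but not with pairs averaged on the deposited scale. AT3G25840, encoding the kinase PRP4KA, was at 0.567 ± 0.248 in WT and 1.02 ± 0.111 in psaf (log2 difference 0.97, limma adjusted p = 0.00624 over 12 arrays and 0.0767 over pair means). WT arrays 3 and 4 were again the lowest, at 0.280 and 0.285, the neighbour correction brought the difference to 0.55, and leaving out both arrays brought it to 0.53. With pairs averaged it passed after the neighbour correction (adjusted p = 0.00549), median centring (0.0421) and cyclic loess (0.0489). AT1G01730 and AT3G25840 are on probe numbers 2840 and 2842, so their low values on WT arrays 3 and 4 may be a single run of neighbouring probes. AT2G44760 was at 1.03 ± 0.385 and 1.71 ± 0.175 (log2 difference 0.80, adjusted p = 0.005 and 0.0705), and leaving out WT arrays 1 and 2, which read 0.636 and 0.592 against 1.06 to 1.43 on the other WT arrays, lowered the difference to 0.47. With pairs averaged it passed after the neighbour correction (0.90, adjusted p = 0.00289) and median centring (1.16, adjusted p = 0.0262). The protein kinase gene AT1G53050 was at 0.840 ± 0.387 and 1.4 ± 0.277 (log2 difference 0.83, adjusted p = 0.0399 and 0.111), with 5 of 6 psaf arrays above the WT mean. Its 12-array call also ended when any of psaf arrays 1 to 5 or WT arrays 3, 4 or 6 was left out, with log2 differences of 0.68 to 0.86. Without both WT arrays 3 and 4 the difference was 0.45 (adjusted p = 0.207), and after the neighbour correction it was 0.62 (adjusted p = 0.0778).

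All 6 named genes with the largest fall were lower in all 8 fits, and all 6 psaf arrays lay below the WT mean for each. Z-ISO changed by -2.52 ± 0.25 log2 (limma adjusted p = 0.00281 with pairs averaged). AT1G25500, a choline transporter-like gene, fell from 0.287 ± 0.0503 to 0.103 ± 0.00476, a log2 difference of -1.47 (adjusted p = 0.00281). AT2G37580, a RING finger gene, fell from 1.19 ± 0.0994 to 0.438 ± 0.0576, a log2 difference of -1.45 (adjusted p = 0.00281). The MYB-like transcription factor gene AT5G52660 went from 0.248 ± 0.0233 to 0.0952 ± 0.0233, a log2 difference of -1.41 with an SE of 0.21. The psaf means of AT1G25500 and AT5G52660 lay below the offset of 0.106, the intensity of the dimmest 5% of values above 0, and with that offset their differences were -0.90 and -0.82. AT3G52550 went from 0.988 ± 0.213 to 0.374 ± 0.0817, and AT5G06930 from 1.88 ± 0.258 to 0.720 ± 0.0448. Under cyclic loess the Z-ISO difference was -2.23, and those of the other 5 genes lay between -1.15 and -1.01.

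**Figure D2:**
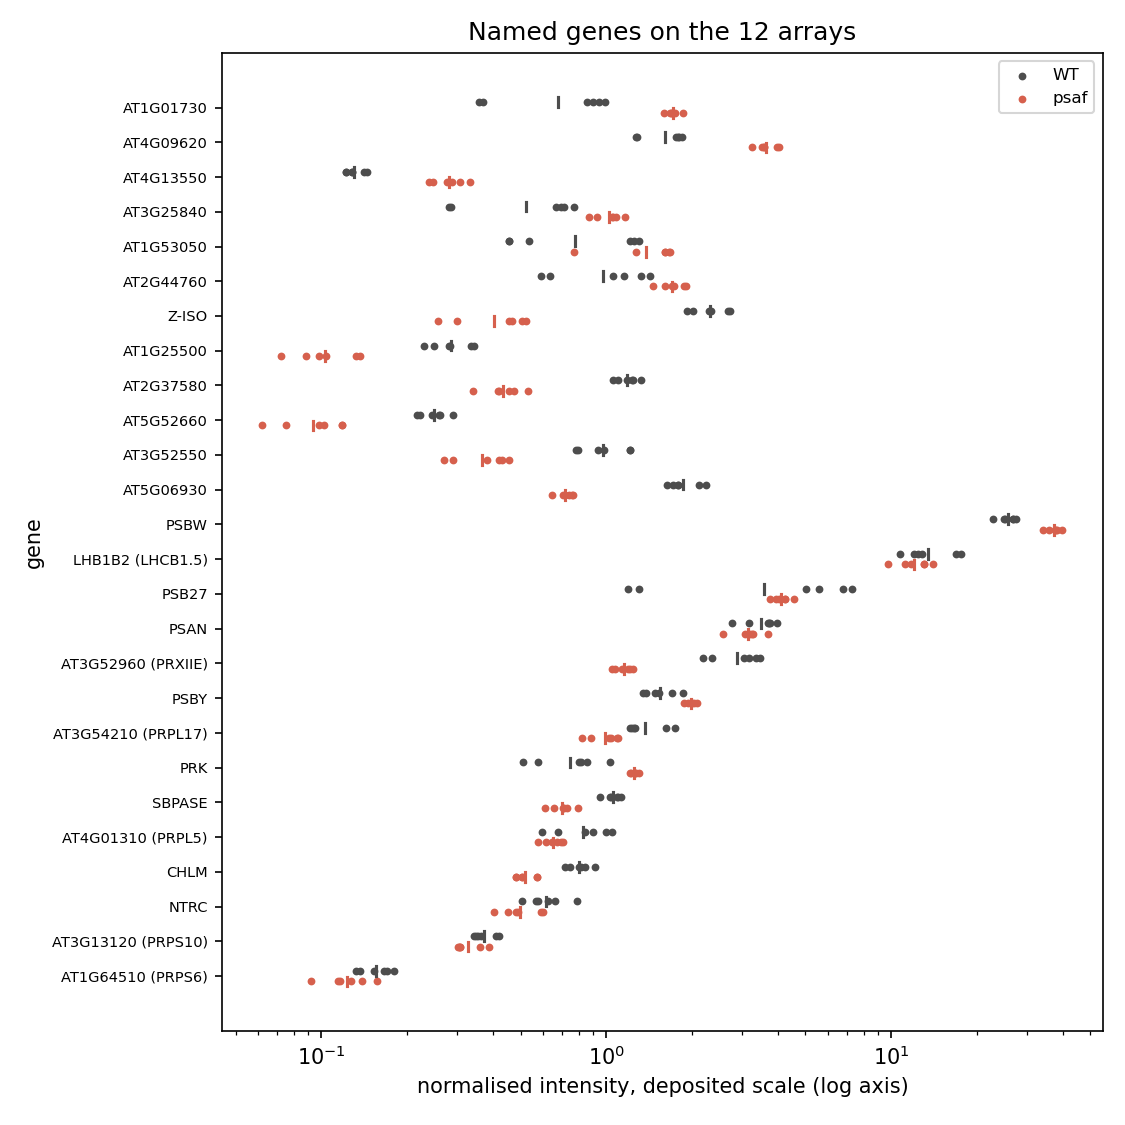
Normalised intensity on the deposited scale (log horizontal axis) of the named genes, with 1 dot per array, WT in grey and psaf in red, and a vertical tick at each genotype's geometric mean. Z-ISO shows the widest gap, with WT arrays between 1.91 and 2.71 and psaf arrays between 0.256 and 0.522; for PSB27 the WT arrays 1 and 2, at 1.3 and 1.19, stand apart from the other 4.

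The photosystems were represented by few named probes. In the list of photosystem I core subunits 1 of 11 genes was tested, and in the antenna list 1 of 20. PSAN (AT5G64040), a lumenal photosystem I subunit, was at 3.52 ± 0.488 in WT and 3.17 ± 0.338 in psaf (limma adjusted p = 0.246 over 12 arrays). The antenna gene LHB1B2 (AT2G34420, LHCB1.5) was at 13.7 ± 3.06 and 12.1 ± 1.41 (adjusted p = 0.294). Its log2 difference of -0.17 became -0.47 under cyclic loess, where it passed over 12 arrays (adjusted p = 0.00589) but not over pair means (0.0866), and 0.19 under median centring. For PSAN cyclic loess gave -0.26 (adjusted p = 0.0363 over 12 arrays, 0.202 over pair means), median centring gave 0.21, and leaving out WT arrays 5 and 6 gave -0.27 (adjusted p = 0.0312). Leaving out WT arrays 1 and 2 gave -0.07 for PSAN (adjusted p = 0.599), and leaving out psaf arrays 1 and 2 gave -0.06 (adjusted p = 0.645). The PSAF transcript itself, the target of the antisense construct, was on no probe with 1 named gene and was not analysed here, so the genotype labels were not checked by it.

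In the list of photosystem II subunits 3 of 14 genes were tested, and 2 of them passed over 12 arrays, both higher in psaf; 1 passed with pairs averaged, and 2 passed in both fits when adjusted over the list alone. PSBW (AT2G30570) rose on the deposited scale from 25.7 ± 1.7 to 37.3 ± 2.06 (log2 difference 0.54 ± 0.11, limma adjusted p = 0.0108 over pair means). The PSBW difference was 0.15 under cyclic loess, 0.17 under quantile normalisation and 0.27 after the neighbour correction, and it passed in none of these. Under median centring it was 0.89 and passed (limma adjusted p = 0.00595 over pair means). The WT arrays read 22.9 to 27.5 for PSBW, with no close pair standing apart, so the fall to 0.27 may come from the correction itself. PSBY (AT1G67740) was at 1.55 ± 0.215 and 1.99 ± 0.0698 (log2 difference 0.37, adjusted p = 0.00185 over 12 arrays and 0.065 over pair means); over pair means it passed after median centring (0.72, adjusted p = 0.0198), cyclic loess (0.45, 0.0403) and the neighbour correction (0.38, 0.0204). PSB27 (AT1G03600), a photosystem II assembly factor, was at 4.52 ± 2.97 and 4.13 ± 0.271 (adjusted p = 0.713). Its linear mean was lower in psaf while its mean log2 difference was 0.20, because the low WT arrays weigh more on the log scale, so no direction is given. PSB27 read 1.3 and 1.19 on WT arrays 1 and 2 and 5.02 to 7.30 on the other WT arrays. Without WT arrays 1 and 2 the log2 difference was -0.57 (adjusted p = 9.41e-04), after the neighbour correction it was -0.39 (adjusted p = 9.74e-04 over 12 arrays and 0.0178 over pair means), and with array weights or without WT array 1 or WT array 2 alone it was -0.12, -0.09 and -0.12.

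In the Calvin-Benson list 2 of 24 genes were tested, and they moved in opposite directions, both in the fit over 12 arrays and with pairs averaged; both passed when adjusted over the list alone. PRK rose by a log2 difference of 0.75 ± 0.20 (limma adjusted p = 0.0286 over pair means) and was higher in all 8 fits, with 6 of 6 psaf arrays above the WT mean. The difference in PRK was 1.04 under cyclic loess and 0.61 after the neighbour correction. WT arrays 1 and 2 read 0.508 and 0.576 for PRK, against 0.801 to 1.03 on the other WT arrays. SBPASE (AT3G55800), sedoheptulose-bisphosphatase of the same cycle, fell on the deposited scale from 1.05 ± 0.0146 to 0.700 ± 0.0649, a log2 difference of -0.59 (adjusted p = 0.00859). Relative to the median probe the SBPASE difference was -0.30, and under cyclic loess it was -0.28 with an adjusted p of 0.115 over pair means.

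In the tetrapyrrole list 1 of 29 genes was tested. CHLM (AT4G25080), magnesium protoporphyrin methyltransferase of chlorophyll synthesis, fell on the deposited scale from 0.805 ± 0.0639 to 0.519 ± 0.0212, a log2 difference of -0.63 (limma adjusted p = 0.00667 over pair means); under cyclic loess the difference was -0.27 with an adjusted p of 0.0994 over pair means. In the redox list 2 of 32 genes were tested, 2 passed over 12 arrays, both lower in psaf, and 1 passed with pairs averaged; the counts adjusted over the list alone were also 2 and 1. AT3G52960 (PRXIIE) fell by 1.33 on the log2 scale (adjusted p = 0.00346 over pair means) in 6 of 6 psaf arrays and was lower in all 8 fits. NTRC (AT2G41680), the plastid NADPH thioredoxin reductase, was at 0.617 ± 0.0726 and 0.503 ± 0.0816 (adjusted p = 0.0477 over 12 arrays and 0.169 over pair means). The NTRC difference of -0.30 became 0.05 under quantile normalisation and median centring and 0.08 under cyclic loess, and after the neighbour correction it was -0.32 (adjusted p = 0.046 over pair means). Its 12-array call ended without any of WT arrays 1, 2, 4, 5 and 6 or psaf arrays 3 to 6, at -0.32 to -0.23.

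In the list of plastid ribosomal proteins 4 of 31 genes were tested. In the 12-array fit 3 passed, all lower in psaf on the deposited scale, none passed with pairs averaged on the deposited scale, and the counts adjusted over the list alone were 4 and 0. PRPL17 (AT3G54210) was at 1.38 ± 0.254 in WT and 0.993 ± 0.123 in psaf (log2 difference -0.47, limma adjusted p = 0.00314 over 12 arrays and 0.0669 over pair means). PRPL5 (AT4G01310) differed by -0.35 and PRPS6 (AT1G64510) by -0.34, with adjusted p = 0.184 and 0.115 over pair means. PRPS10 (AT3G13120) differed by -0.19 (adjusted p = 0.066 over 12 arrays). With pairs averaged, PRPL17 (-0.45, adjusted p = 0.00697) and PRPL5 (-0.44, adjusted p = 0.00409) passed after the neighbour correction. Under cyclic loess PRPL17 was at -0.24 (adjusted p = 0.0832 over 12 arrays), PRPL5 at -0.0015, PRPS6 at 0.06 and PRPS10 at 0.22, so the members did not share a direction under that scaling. The 12-array call for PRPL5 ended without any of WT arrays 3 to 6 or psaf arrays 2 to 5 (-0.36 to -0.28). Without both WT arrays 5 and 6 the PRPL5 difference was -0.19 (adjusted p = 0.185), and without both WT arrays 1 and 2 it was -0.54 (adjusted p = 3.17e-04). The 12-array call for PRPS6 ended without any of WT arrays 3, 4 and 6 or psaf arrays 1, 5 and 6 (-0.33 to -0.26). PRPS10 passed without psaf array 3 (-0.24) or psaf array 4 (-0.22). It also passed with array weights (-0.24, adjusted p = 0.0249) and with the replicate number as a block (-0.19, adjusted p = 0.00536).

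None of the lists of electron transport and ATP synthase, carotenoid and isoprenoid biosynthesis, plastid proteases and chaperones, protein import and thylakoid targeting, starch metabolism, amino acid and nitrogen assimilation, or non-green tissue and senescence markers had a tested gene on a probe with 1 name. Z-ISO is not in the carotenoid list as it was fixed. No list reached the 5 measured members set for a list test. The photosynthesis lists were therefore joined after seeing the data, and their 7 genes lay on average 0.43 log2 above the median probe (limma camera adjusted p = 0.0516 with the preset correlation, adjusted p = 0.0891 with an estimated correlation). This difference was 0.11 under quantile normalisation and 0.07 under cyclic loess (adjusted p = 0.699 and 0.859). The 7 joined genes of other plastid functions lay at -0.22 (adjusted p = 0.152, and adjusted p = 0.171 with an estimated correlation).

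**Figure D3:**
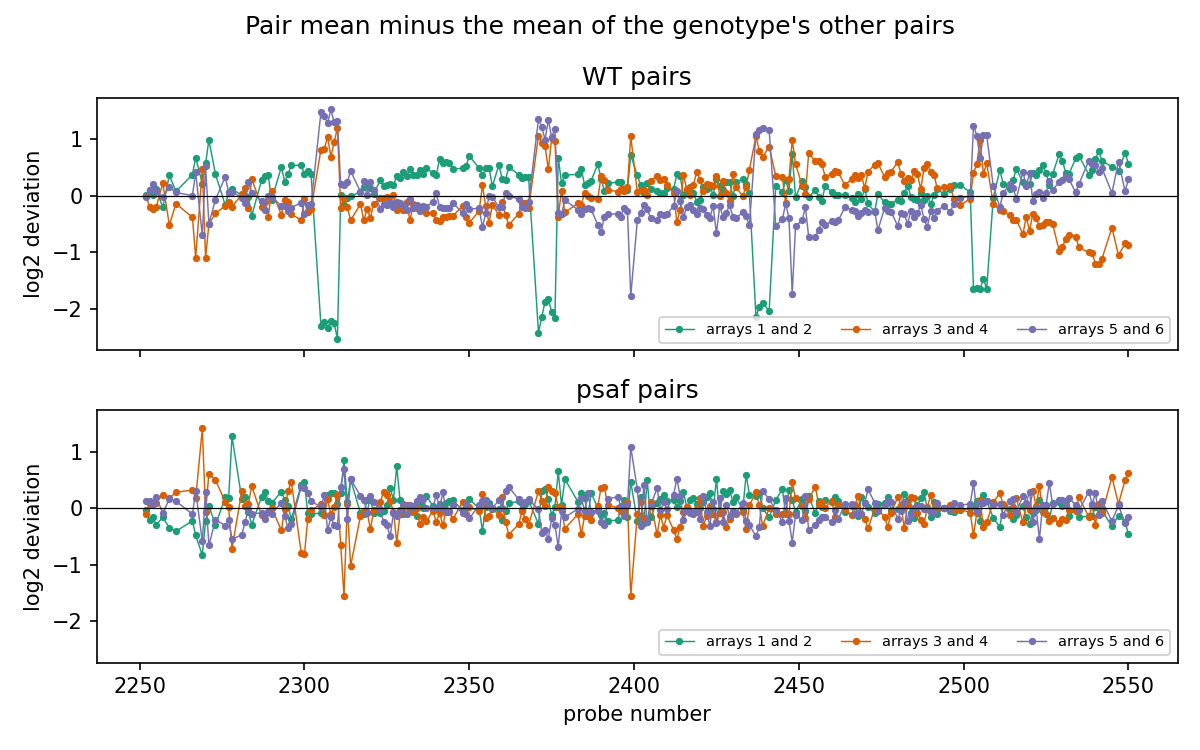
Log2 deviation of each close pair of arrays from the mean of the other pairs of its genotype (vertical axis) along the probe number (horizontal axis), for a stretch of probes, with WT pairs in the upper panel and psaf pairs in the lower panel. Runs of neighbouring probes deviate together on WT pairs; over all probes the correlation between neighbouring probes was 0.657 to 0.745 for WT pairs and 0.127 to 0.198 for psaf pairs.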

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

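The settings with averaged pairs and another scaling, the neighbour correction, the named background and the leaving out of close pairs were chosen after seeing the data. The count of 1997 probes (359 higher, 1638 lower) stayed within 1.5 times under the offset, the filters, the variance models, the array weights, the exact Wilcoxon test (1909) and the neighbour correction (2249). Without single arrays it was 1892 to 1973 (higher 321 to 357, lower 1560 to 1626), and without a close pair 1783 to 2073 (higher 286 to 388, lower 1466 to 1711). With the replicate number as a block it was 2148. The numbers were not taken to pair the arrays, because only 4 of 6 same-numbered WT and psaf arrays correlated in their deviations above 0.1 (0.01 to 0.30); that 8 of 12 arrays correlated best with their own number is a hint of shared numbers from the data, not the design. The block moved PRPS10 (AT3G13120) past the threshold (-0.19, adjusted p = 0.00536) and no other named gene. Averaging pairs left 1271 calls (157 higher), and a random block for pairs, which keeps all 12 arrays, left 1442 (228 higher). Other scalings changed the split, to 725 higher and 854 lower (quantile), 926 and 722 (median centring) and 823 and 797 (cyclic loess). With pairs averaged as well, the totals were 699, 757 and 765, with 410, 329 and 405 lower. A threshold of 0.01 left 236 higher, and a minimum of 1.5-fold left 967, 132 higher and 835 lower. The joined photosynthesis list (0.43, adjusted p = 0.0516) passed with the replicate block (0.43, adjusted p = 0.0497), the offset (0.36, 0.0492), the named background (0.48, 0.0254) and fry (0.49, 7.96e-06). With an estimated correlation in camera this list did not pass (adjusted p = 0.0891, and 0.17 with pairs averaged too). Over its other alternatives the adjusted p reached 0.887. Without single arrays it was 0.39 to 0.46, passing without WT array 1, 2 or 4 or psaf array 1, 2, 3 or 4, and without a close pair 0.36 to 0.48, passing without psaf arrays 1 and 2, WT arrays 3 and 4 or psaf arrays 3 and 4. The other plastid list passed by fry alone (-0.16, adjusted p = 0.00199). For both lists fry took the 12 arrays as independent and was not run on pair means, so its p-values do not allow for the close pairs. Over 26 named genes and all alternatives, 772 results kept their direction and side of the threshold, 95 lost the call, 10 gained it and 29 changed sign, 13 of these at values past the threshold in neither setting. PSB27 reversed to -0.39 under the neighbour correction, to -0.39 with pairs averaged too, to -0.12 with array weights and to -0.57 without WT arrays 1 and 2, in a range up to 0.68 without other close pairs. NTRC reversed to 0.0536, 0.0510 and 0.0799 under quantile, median and loess scaling, and to 0.0593, 0.0510 and 0.0815 with pairs averaged. Median centring reversed PRPL5 (AT4G01310) to 0.0065 and, with pairs averaged, 0.0064. PRPS6 (AT1G64510) reversed to 0.0094 and 0.0554 under median and loess scaling and to 0.0093 and 0.0684 with pairs averaged. PRPS10 (AT3G13120) reversed to 0.22 under cyclic loess (adjusted p = 0.0464), 0.16 under quantile and 0.16 under median scaling, and to 0.22, 0.16 and 0.16 with pairs averaged. Median centring turned LHB1B2 to 0.19 (0.19 with pairs averaged) and PSAN to 0.21 (0.21 with pairs averaged), and leaving out close pairs gave LHB1B2 -0.28 to 0.0085. NTRC, PRPL5, PRPS6 and PRPS10 lay at -0.05 to 0.10 log2 relative to the median probe on the deposited scale, and only PRPS10 lay above it. Median centring removes each array's own median and left the median probe at 0.058. Small negative values relative to the median probe therefore turned positive under it. LHB1B2 and PSAN lay at 0.13 and 0.15 relative to the median probe, so that their positive sign under median centring follows. For PSB27 the values without WT arrays 1 and 2 are above, and otherwise the cause was not tested. The planned PSAF result and the tests of single lists were not run, since PSAF was not analysed here and no list had 5 measured members. What the 173 probes not tested would show is open, since background was not measured and a 0 may be missing or low.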

Other observations

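Other named genes, chosen after their values were seen from those called in the same direction in all 8 fits, fell or rose in psaf as follows (pair means, SD, n = 3; limma adjusted p with pairs averaged). ATAB2 (AT3G08010), an RNA-binding protein required for light-controlled translation of photosystem I and II proteins, fell from an intensity of 0.172 ± 0.0198 to 0.0840 ± 0.0110, a log2 difference of -1.04 (adjusted p = 0.00422); its psaf mean lies below the offset of 0.106, with which the difference was -0.55 (adjusted p = 0.0056). CYN (AT3G23490), a cyanase, fell from 2.18 ± 0.0607 to 1.19 ± 0.1 (adjusted p = 0.00337). The DNA glycosylase gene DME (AT5G04560) fell by 1.03 on the log2 scale, the F-box gene FBL17 (AT3G54650) by 0.98 and the transcription factor gene TCP15 (AT1G69690) by 0.95. With the offset their differences were -0.83, -0.68 and -0.77, and under cyclic loess they were -0.63, -0.57 and -0.55. Genes that rose included XERICO (AT2G04240), a RING finger gene linked to abscisic acid accumulation, from 3.42 ± 0.250 to 5.03 ± 0.222 (log2 difference 0.56, adjusted p = 0.00956). The calmodulin-like gene CML30 (AT2G15680) rose from 1.23 ± 0.0609 to 1.89 ± 0.0892 (log2 difference 0.62, adjusted p = 0.00609). The kinase gene ATSIK (AT3G08760) rose by a log2 difference of 0.44 (adjusted p = 0.0478). These genes share no list fixed beforehand, and no theme was tested for them.

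The tests of an additive background, of the brightest probes, of local patches, of co-regulated neighbours and of patches under the photosynthesis list were chosen only after the result was seen; those of dim-probe noise, of list brightness and of other splits were chosen before.

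The median probe was 0.29 log2 lower in psaf although array totals were alike. A lower additive background on psaf arrays would give about equal linear differences in dim and middle probes. The ratio of the seventh to the dimmest of 10 brightness classes was 6.44 (bootstrap 4.51 to 8.75), and that of the fifth was 4.26 (3.35 to 5.79). But the dimmest class had a median intensity of 0.121 and values of 0 were dropped, so it had little room for the 0.167 of the seventh. From the sixth to the ninth class the linear WT minus psaf difference was about equal, at 0.162 to 0.172, and in the brightest it was -0.369. The ratio therefore does not decide on an additive background. A candidate explanation is a fixed total with more signal on bright probes: the brightest 1% (35 probes) held 23.6% ± 0.168 of the signal in WT and 28.9% ± 0.828 in psaf (SD, n = 3), and scaling without them moved the shift to -0.16. That lies past the bound set against this cause by less than the SD of the pair medians (0.0280 in WT and 0.0451 in psaf), so the test does not decide. Scaling without the brightest 10% (344 probes) moved the shift to -0.002. The lower brightness classes all lay at -0.40 to -0.19, so scaling to their own total recentres the median and cannot decide either. Whether psaf plants differ in the bright transcripts or the arrays were handled differently by genotype stays open and untested.

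On WT arrays, deviations of a close pair from the other pairs ran along neighbouring probe numbers, with a correlation between neighbours of at least 0.657 in each of the 3 WT pairs, against at most 0.0758 after shuffling probe order; the 3 deviations sum to 0 at each probe, so a patch on 1 pair enters all 3 values and they are not separate observations. Noise of dim probes is argued against by a value of at least 0.312 in the brightest 25% of probes, and co-regulated neighbours, as the whole cause, by the lower values of 0.127 to 0.198 in psaf pairs, which also exceeded their shuffles (at most 0.0563), and of 0.113 for the genotype difference. Arrays of a WT pair shared the deviations (correlations of 0.863 to 0.943 across probes, which are not independent replicates), which is consistent with signal gained or lost locally in something a pair shares. Probes over 2-fold low numbered 229 on WT arrays 1 and 2, 100 on arrays 3 and 4 and 9 on arrays 5 and 6, which had 123 over 2-fold high, against 7 to 24 low and 6 to 13 high on psaf pairs. PSB27, AT1G01730, AT3G25840, PRK and AT1G53050 are genes whose WT values may carry such patches, and no biological explanation was tested. For AT1G53050 this concerns WT arrays 3 and 4. AT2G44760 was also low on WT arrays 1 and 2, but the neighbour correction did not lower its log2 difference (0.80 before, 0.90 after), so a patch there stays open. AT1G01730 and AT3G25840 are on near probe numbers and may share a single patch.

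The 7 joined photosynthesis genes lay 0.43 log2 above the median probe. Their mean difference of 0.14 was at percentile 65.6 of 10000 random lists matched on brightness (matched median 0.07, 95% of lists from -0.31 to 0.41). After the neighbour correction the shift was 0.27 (limma camera adjusted p = 0.111). The correction was not tested on probes outside patches, so part of this fall may come from the correction itself. Brightness of the listed probes and local patches on WT arrays therefore both stay open as explanations, and a joint rise of photosynthesis transcripts is not shown. A response of these genes to the lack of PSI-F stays open as well.

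Of 100 splits of the 12 arrays, 1, the real one, gave 1997 probes, and the highest of the others gave 0, but this count treats the arrays of a close pair as independent and so does not by itself exclude chance. Of the 10 splits of the 6 pair means, 1, again the real one, gave 1271 probes and the highest other gave 0, but 10 splits are too few for a share under 0.05. In both cases every other split mixed the genotypes, which puts the large genotype difference into the spread within groups. Counts near 0 were therefore likely in advance for the other splits. For no named gene or array measure among 58 tested groups of 6 arrays did a single array stand apart by Dixon's criterion, which cannot see a close pair that stands apart together.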
